A study of Mus musculus with 16 samples.

How the data were processed

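RNA from whole liver of 16 male mice aged 7 days was measured on one-colour Affymetrix whole-transcript arrays, 1 array per animal and 4 animals per genotype. Per the labels, 100 ng of RNA with an integrity number above 8.0 entered each labelling reaction. The 4 genotypes were WT (littermates without Cre that carry the floxed alleles), mice lacking TRAF2 and caspase-8 in liver parenchymal cells through alfp-Cre (TRAF2/Casp8 KO), mice that in addition lack RIPK3 in the whole body (RIPK3 triple KO), and mice that in addition lack IKKβ in liver parenchymal cells (IKKβ triple KO).

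The deposited table holds log2 values that the authors made with RMA; the version of RMA, the software and the probe set definition are not given in the sources used here. The log base was read from the values, which run from 0.89 to 13.65. All 16 value columns were used and 0 per-sample columns were left unused. Array medians lay between 4.90 and 5.05. The number of arrays limits the precision.

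No further normalisation or filter was applied. All 35556 probe sets were tested, of which 21218 carry 1 gene symbol, 1881 carry several and 12457 carry none. For statements on genes, the probe set with the highest mean over all arrays among those with 1 symbol stood for its gene, which gave 18820 genes. Group means were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided) in 1 model of the 4 genotypes over all 16 arrays, and p-values were adjusted by Benjamini-Hochberg over all probe sets at a threshold of 0.05. Every adjusted p of a gene is from this limma model. Checked on simulated data with the spread of these arrays, the procedure recovered 43.9% of changes of 0.5 on the log2 scale, 92.2% of changes of 1 and 98.2% of changes of 2, and 6.47% of its calls were false.

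The 31 gene lists tested (607 genes written over all lists, 534 measured) were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, with camera's estimated correlation beside it. limma's fry, which tests whether a list's genes move on balance in 1 direction and compares them with no other genes, was run beside these. The p-values of each test were adjusted over 186 tests (31 lists in 6 comparisons). Of them, 76 passed with the preset correlation and 0 with an estimated correlation. Members past the threshold were counted over all probe sets and, separately, adjusted over the list alone.

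The genotypes, the 3 main comparisons and 3 further ones, the test, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Named genes were the 4 targeted genes, the 8 largest rises and 8 largest falls of each main comparison (4 and 4 of each further one) among genes past the threshold whose groups did not overlap, leaving out predicted, clone-named, small RNA, antigen receptor segment, olfactory and vomeronasal genes. For each list described, up to 4 members past the threshold with the smallest adjusted p were named, or up to 2 given as values where none passed.

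The alternatives were an intensity trend with robust eBayes, a model of only the 2 groups compared, leaving out the dimmest of 3 equal parts of the probe sets, quantile normalisation again, centring each array on its median, 1 probe set per gene, array weights, a replicate block, the plate row as a random block, a minimum fold of 2, and leaving out each array in turn. Plate positions were read from the array names, a reading that was not checked against a plate layout. By it, WT and IKKβ triple KO arrays were in column 5, and TRAF2/Casp8 KO and RIPK3 triple KO arrays in column 7. WT and RIPK3 triple KO arrays were in rows A to D, and the others in rows E to H. TRAF2/Casp8 KO replicate 4 alone has another array-name prefix; it was kept, and the counts without it are given with each comparison it enters. A column term cannot be estimated beside the 4 genotypes. To measure how much of a difference other genotypes share, genes were called on 2 arrays per group and their shift was measured on the other 2, over all 36 splits, without the targeted genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.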

Results

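The data are log2 signals of 35556 probe sets in 16 livers of 7-day-old male mice, with 4 animals in each of 4 genotypes. TRAF2 is an adaptor of TNF receptor signalling, caspase-8 starts death-receptor apoptosis and restrains necroptosis, RIPK3 is the kinase that drives necroptosis, and IKKβ is a kinase of the canonical NF-κB pathway. The series title places NF-κB and the carcinogenic potential of liver necroptosis at the centre of the study. Correlations between arrays of a genotype lay between 0.981 and 0.991. The first principal component (15.58% of the variance) placed WT at −28.75 to −12.26 and IKKβ triple KO at −20.96 to −13.13, against 4.91 to 17.78 for TRAF2/Casp8 KO and 19.87 to 35.19 for RIPK3 triple KO. That order is also the order of the plate columns as read from the array names: WT and IKKβ triple KO in column 5, the other 2 genotypes in column 7. WT and RIPK3 triple KO were in rows A to D and TRAF2/Casp8 KO and IKKβ triple KO in rows E to H, so each genotype filled a part of the plate of its own, and plate position as a whole cannot be told apart from genotype in any comparison. WT replicate 1 stood apart from the 15 others on the second component (−50.50 against −22.31 to 27.04) and had the lowest array weight, 0.461.

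Casp8, Ripk3 and Ikbkb signals were low in the genotypes labelled as lacking them, and Traf2 went the other way. Casp8 was 9.87 ± 0.14 in WT (mean and SD, n = 4) and lower in all 12 arrays labelled as deleted, by a log2 difference of −0.91 in TRAF2/Casp8 KO (limma adjusted p = 0.000323), −1.18 in RIPK3 triple KO (2.69e-05) and −0.99 in IKKβ triple KO (0.00289). Ripk3 lay at 4.07 to 4.40 in RIPK3 triple KO and at 5.62 to 6.42 in the 12 other arrays. Ikbkb was lower in IKKβ triple KO than in TRAF2/Casp8 KO by 1.62-fold (log2 −0.69 ± 0.09 SE, adjusted p = 0.00137), while its difference from WT was −0.45 (adjusted p = 0.175). Traf2 read 6.28 ± 0.08 in WT, but 7.30 ± 0.16 in the arrays labelled TRAF2/Casp8 KO, 7.32 ± 0.15 in those labelled RIPK3 triple KO and 6.89 ± 0.02 in those labelled IKKβ triple KO. The signal was thus higher in all 12 arrays labelled as Traf2-deleted, by 2.03-fold in TRAF2/Casp8 KO (adjusted p = 2.14e-05). Xist read 2.30 to 3.03 and Uty 6.71 to 7.48 over the 16 arrays, which the labels give as male.

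**Figure D1:**
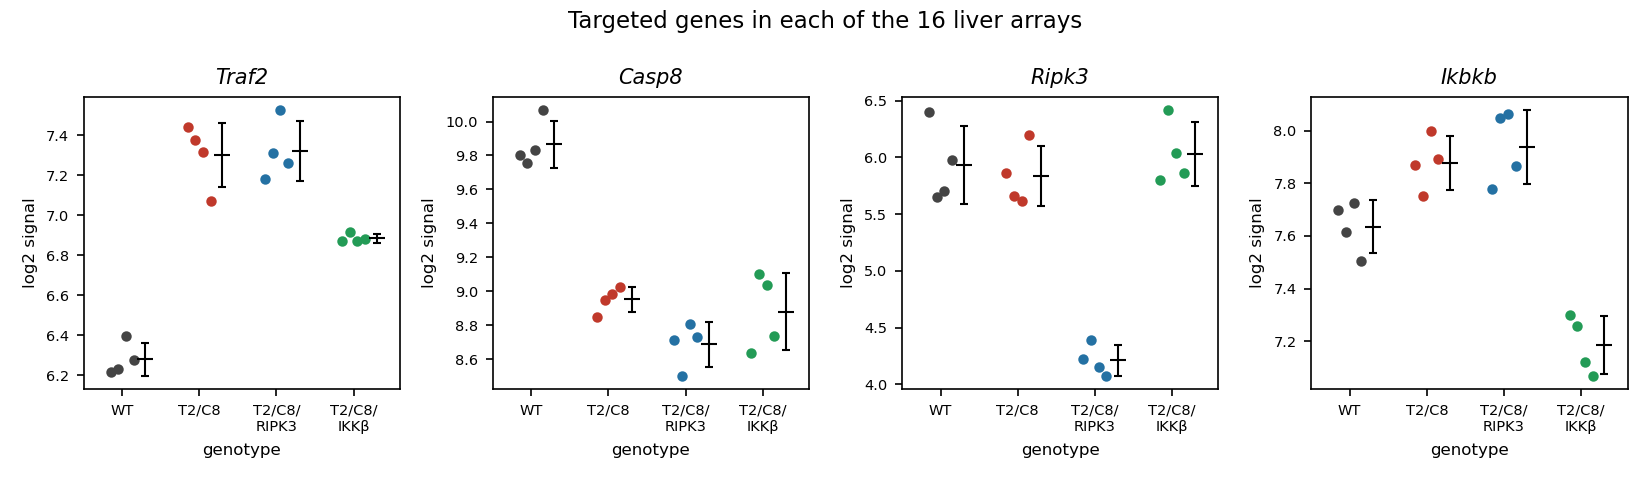
Log2 signal (y axis) of Traf2, Casp8, Ripk3 and Ikbkb by genotype (x axis); each point is 1 array, and the bar beside the points is the mean with the SD (n = 4). Traf2 lies at 6.21 to 6.40 in WT and above that range in all 12 arrays labelled as deleted, while Casp8 lies below WT in all 12.

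The comparison of the arrays labelled TRAF2/Casp8 KO with WT asks what joint loss of TRAF2 and caspase-8 in parenchymal cells does to the liver. Among genes that passed, 9 of 31 canonical NF-κB targets and 6 of 12 non-canonical NF-κB genes rose, and 2 of 21 drug-metabolising enzymes and 4 of 15 urea cycle and amino acid genes fell. Ubd, a ubiquitin-like protein induced by TNF and interferon-γ, rose 70.9-fold (log2 6.15 ± 0.23 SE, n = 4 per group, adjusted p = 2.02e-09). Nfkb2, which encodes the p100 precursor of the non-canonical pathway, rose 4.13-fold (log2 2.05 ± 0.18, adjusted p = 1.8e-05), and the inhibitor gene Nfkbie rose 5.61-fold (log2 2.49 ± 0.22, adjusted p = 1.8e-05). The cytochrome P450 genes Cyp2c29 and Cyp2b10 fell by 5.94-fold and 3.58-fold (adjusted p = 0.00379 and 0.000231). The direction for Traf2 itself went against the label, as given above.

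After Ubd, the largest rises were in Guca2b, which encodes uroguanylin (17.3-fold, log2 4.12 ± 0.35), Rragd, a GTPase of nutrient sensing (14.2-fold), Wif1, a secreted Wnt inhibitor (13.6-fold), the carboxylesterase gene Ces3a (12.8-fold), the trefoil factor gene Tff3 (10.4-fold), Siglecf, a sialic-acid-binding lectin (9.76-fold), and Serpina12, which encodes vaspin (8.71-fold). The largest falls were in the steroid dehydrogenase gene Akr1c18 (8.5-fold, log2 −3.09 ± 0.55, adjusted p = 0.00624), the protease inhibitor genes Mug1 (6.33-fold) and Mug2 (3.92-fold), Cyp2c29, the transporter gene Slc22a26 (5.4-fold), Tdo2, which opens tryptophan breakdown (4.03-fold), Clec2h (3.64-fold) and Cyp2b10. The call of Tdo2 was lost without WT replicate 2, 3 or 4 or TRAF2/Casp8 KO replicate 1, 2 or 4 (adjusted p up to 0.102). That of Mug2 was lost without any array but WT replicate 4 (up to 0.125), and that of Clec2h without WT replicate 2, 3 or 4 or TRAF2/Casp8 KO replicate 4 (up to 0.0691).

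Of 12 measured non-canonical NF-κB genes, 6 rose, 0 fell and 6 did not pass (8 higher and 1 lower adjusted over the list alone). Examples were Nfkb2, the lymphotoxin gene Ltb (log2 2.45), Birc2 (1.12) and the adhesion gene Madcam1 (1.96). The list median was 0.82 (camera adjusted p = 4.54e-09, adjusted p = 0.312 with an estimated correlation). Of 31 canonical NF-κB targets, 9 rose and 0 fell (11 and 1 adjusted over the list alone), among them Nfkbie, the chemokine genes Ccl20 (log2 2.00) and Cxcl10 (3.02), and Tnfaip3, which encodes the inhibitor A20 (1.76). Their median was 0.26 (adjusted p = 2.13e-08, adjusted p = 0.312 with an estimated correlation), but 0.42 without WT replicate 1 and 0.14 without TRAF2/Casp8 KO replicate 4. Of 22 chemokines, 6 rose and 0 fell (7 and 0 adjusted over the list alone), including Ccl9 (1.01) and Cx3cl1 (1.28), with adjusted p = 1.74e-05 and adjusted p = 0.312 with an estimated correlation. In the necroptosis and cell death list, 2 of 20 genes rose (3 adjusted over the list alone), the inhibitor of apoptosis genes Birc2 and Birc3, which the NF-κB lists also hold. That list had adjusted p = 0.00873 and adjusted p = 0.412 with an estimated correlation. Of 24 interferon-stimulated genes, 1 rose (1 adjusted over the list alone), Cxcl10, and the list test gave adjusted p = 0.571; its median was −0.11 and its mean 0.02. The median was −0.22 without WT replicate 3 (adjusted p = 0.0448) and −0.03 without WT replicate 4.

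Of 18 biliary and progenitor genes, 4 rose (6 higher and 2 lower adjusted over the list alone): Sox9 (log2 1.31), the claudin genes Cldn7 (1.35) and Cldn4 (1.76), and Epcam (0.79). The list had adjusted p = 0.00611 and adjusted p = 0.312 with an estimated correlation. Of 18 fetal liver and cancer-associated genes, 4 rose (7 adjusted over the list alone): Tff3, Sprr1a (2.41), Bex1 (2.23) and Myc (0.77). That list had adjusted p = 1.33e-06 and adjusted p = 0.312 with an estimated correlation. Of 16 AP-1 and immediate early genes, 3 rose (9 adjusted over the list alone), Maff (1.03, with overlapping groups), Klf6 (0.50) and Myc, with a median of 0.53 (adjusted p = 1.21e-06, adjusted p = 0.312 with an estimated correlation). Of 26 stellate cell and matrix genes, Col6a3 (0.79) and Ccn2 (0.80) rose (3 adjusted over the list alone; adjusted p = 6.52e-06, adjusted p = 0.312 with an estimated correlation). Cd74, the invariant chain of MHC class II, rose 3.6-fold. Of 20 monocyte and macrophage genes, Cd9 rose (0.92, 1 adjusted over the list alone), with a list median of 0.145 (0.0252 to 0.348 with 1 array left out). That list had camera adjusted p = 0.0383 and adjusted p = 0.813 with an estimated correlation. The first was up to 0.232 without WT replicate 2, 3 or 4 or TRAF2/Casp8 KO replicate 4.

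Of 15 urea cycle and amino acid genes, 4 fell (6 adjusted over the list alone): Hal (log2 −1.56), Hpd (−0.68), Tdo2 and Agxt (−0.79). That list had adjusted p = 3.37e-05 and adjusted p = 0.43 with an estimated correlation. Of 19 hepatocyte secreted and identity genes, Apoc3 fell (log2 −1.21, 1 adjusted over the list alone), with a list median of −0.095. The hepatocyte list had camera adjusted p = 0.00237 and adjusted p = 0.581 with an estimated correlation. Of 21 drug-metabolising enzymes, Cyp2c29 and Cyp2b10 fell (1 higher and 4 lower adjusted over the list alone; adjusted p = 0.000541, adjusted p = 0.396 with an estimated correlation). Among bile acid genes, Baat, which conjugates bile acids, rose 4.97-fold and the nuclear receptor gene Nr0b2 fell by 1.75-fold, and the list test gave adjusted p = 0.571. Among 26 acute phase genes, Il1rn rose (log2 1.84), and Saa3 (−1.52) and Saa4 (−0.76) fell (1 and 6 adjusted over the list alone). The acute phase list test gave adjusted p = 0.000793, which was 0.0647 without WT replicate 1, and adjusted p = 0.498 with an estimated correlation. Erythroid markers had a median of −0.51 (camera adjusted p = 0.0661). Neutrophil and myeloid precursor markers had a median of −0.29 (camera adjusted p = 0.0884), and both calls changed with single arrays left out. The erythroid list passed without WT replicate 1, 3 or 4 or TRAF2/Casp8 KO replicate 3 or 4 (−0.83 without the last), and its median was −0.21 without WT replicate 2 and −0.29 and −0.25 without TRAF2/Casp8 KO replicate 1 and 2. The neutrophil and myeloid precursor list passed without WT replicate 3 (−0.56) or 4 or TRAF2/Casp8 KO replicate 4 (−0.51). Its median was −0.01 without WT replicate 1 and −0.14 without TRAF2/Casp8 KO replicate 1.

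In all, 800 probe sets passed, 513 higher and 287 lower. They covered 408 higher and 215 lower genes, of which 145 differed at least 2-fold. The groups did not overlap in 11.6% of genes, against 2.86% by chance. The count was 509, 468 and 518 without WT replicate 2, 3 and 4, and 420 and 443 without TRAF2/Casp8 KO replicate 1 and 4. The 2 genotypes were in different plate columns and rows, so a part played by plate position cannot be told apart from genotype here.

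The comparison of RIPK3 triple KO with TRAF2/Casp8 KO asks what changes when the necroptosis kinase is also lost. Of the genes that passed, 34 were higher and 28 lower without RIPK3. Dio1, the deiodinase that activates thyroid hormone, rose 9.75-fold (log2 3.29 ± 0.34 SE, n = 4 per group, adjusted p = 0.000234). Ripk3 fell 3.08-fold (−1.62 ± 0.18, adjusted p = 0.000462), and Ccl2, a monocyte chemoattractant, fell 2.14-fold (−1.10 ± 0.18, adjusted p = 0.0154). The call of Ccl2 was lost without RIPK3 triple KO replicate 3 or TRAF2/Casp8 KO replicate 1 or 4 (adjusted p up to 0.0717).

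The other large rises were in Akr1c18 (8.04-fold), Cyp2c29 (4.91-fold), Cyp2f2 (3.91-fold), the galactosyltransferase gene B3galt1 (3.34-fold), Gdpd3 (2.96-fold), Colgalt2 (2.83-fold, adjusted p = 5.43e-05) and Mettl7b (2.49-fold, adjusted p = 1.69e-05). Large falls were in Samd9l, an interferon-inducible gene (5.14-fold, adjusted p = 0.00743), Dab1 (4.96-fold), the keratin genes Krt20 (3.61-fold) and Krt23 (3.5-fold), Ajuba (2.62-fold) and Cyp1b1 (2.1-fold). The calls of Dio1, Gdpd3, Colgalt2, Mettl7b, Samd9l, Dab1, Ripk3 and Ajuba held with each array left out. Those of Akr1c18, Cyp2c29 and Cyp2f2 were each lost without any of 7 of the 8 arrays (adjusted p up to 0.11, 0.119 and 0.166; the call held without TRAF2/Casp8 KO replicate 2, 1 and 3). That of Krt23 was lost without any of the 8 (up to 0.164), and that of Krt20 without any array but RIPK3 triple KO replicate 2 and TRAF2/Casp8 KO replicate 2 (up to 0.0893). B3galt1 was lost without RIPK3 triple KO replicate 2, 3 or 4 or TRAF2/Casp8 KO replicate 3 or 4 (up to 0.108). Cyp1b1 was lost without RIPK3 triple KO replicate 2 or 3 or TRAF2/Casp8 KO replicate 1, 3 or 4 (up to 0.0764).

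Of 15 urea cycle and amino acid genes, 0 passed over all probe sets and 11 were higher adjusted over the list alone, with a median of 0.51 (camera adjusted p = 2.62e-10, adjusted p = 0.312 with an estimated correlation). Tdo2 differed by 1.77 (adjusted p = 0.17) and Asl by 0.51 (adjusted p = 0.209). Of 19 hepatocyte secreted and identity genes, Apoc3 (0.94) and Gnmt (1.01) rose (2 adjusted over the list alone), with a list median of 0.05. That list had camera adjusted p = 0.0186 and adjusted p = 0.686 with an estimated correlation. The first was up to 0.179 without RIPK3 triple KO replicate 2 or 3 or TRAF2/Casp8 KO replicate 4. Of 23 bile acid genes, Cyp2c70 rose (log2 0.68; 5 higher adjusted over the list alone), with a list median of 0.31 (adjusted p = 1.39e-06, adjusted p = 0.312 with an estimated correlation), but 0.16 without RIPK3 triple KO replicate 3 and 0.20 without TRAF2/Casp8 KO replicate 4. Of 21 drug-metabolising enzymes, Cyp2c29 and Cyp2f2 rose (2 adjusted over the list alone; adjusted p = 0.000541, adjusted p = 0.396 with an estimated correlation). Of 16 AP-1 and immediate early genes, 0 passed and 4 were lower adjusted over the list alone, with a median of −0.42 (adjusted p = 7.93e-06, adjusted p = 0.312 with an estimated correlation). Ier3 differed by −0.86 (adjusted p = 0.118). Of 26 stellate cell and matrix genes, 0 passed and 1 was lower adjusted over the list alone, with a median of −0.15. That list had camera adjusted p = 0.00127 and adjusted p = 0.396 with an estimated correlation. Of 18 fetal liver and cancer-associated genes, 0 passed and 7 were lower adjusted over the list alone (adjusted p = 0.000107, adjusted p = 0.312 with an estimated correlation); Dlk1 differed by −0.93 (adjusted p = 0.0705). Of 18 biliary and progenitor genes, Cldn7 (log2 −1.0) and Krt23 fell (3 adjusted over the list alone; adjusted p = 0.0393, up to 0.116 without RIPK3 triple KO replicate 2 or 3 or TRAF2/Casp8 KO replicate 3, and adjusted p = 0.412 with an estimated correlation).

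Of 31 canonical targets, Ccl2 fell (2 adjusted over the list alone) and the list test gave adjusted p = 0.478. Of 12 non-canonical genes, 0 passed and 2 were lower adjusted over the list alone, Madcam1 at −1.34 (adjusted p = 0.0722) and Ltb at −1.03 (adjusted p = 0.143) having the smallest p. That list had adjusted p = 0.0427, up to 0.128 without RIPK3 triple KO replicate 1, 2 or 3 or TRAF2/Casp8 KO replicate 4, and adjusted p = 0.589 with an estimated correlation. The 17 neutrophil and myeloid precursor markers had a median of −0.98 (0 passed, 0 adjusted over the list alone). That list had camera adjusted p = 7.06e-09 and adjusted p = 0.416 with an estimated correlation. Chil3 differed by −1.28 (limma adjusted p = 0.32). The mean signal of the 17 markers was 7.82 in RIPK3 triple KO replicate 4 and 6.17 to 6.99 in replicates 1 to 3. TRAF2/Casp8 KO arrays read 7.38 to 8.52. The 23 cell cycle genes had a median of −0.42 (0 passed, 0 adjusted over the list alone; adjusted p = 4.17e-08, adjusted p = 0.498 with an estimated correlation). Erythroid markers had a median of −0.56 (0 passed, 0 adjusted over the list alone; adjusted p = 0.163, adjusted p = 0.88 with an estimated correlation). That list passed without RIPK3 triple KO replicate 4 (−1.06) or TRAF2/Casp8 KO replicate 1 or 2, and its median was −0.30 and −0.37 without RIPK3 triple KO replicate 1 and 3 and −0.17 without TRAF2/Casp8 KO replicate 4. Of 17 T and NK cell genes, Gzma fell (−0.62; 1 adjusted over the list alone; adjusted p = 0.000583, adjusted p = 0.396 with an estimated correlation). Of 20 monocyte and macrophage genes, Cx3cr1 fell (−1.0, with overlapping groups; 1 adjusted over the list alone; adjusted p = 0.00228, adjusted p = 0.649 with an estimated correlation).

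In all, 94 probe sets passed, 47 higher and 47 lower. Of the lower ones, 9 list the predicted gene Gm3893. After centring each array on its median, 77 were higher and 45 lower. The 94 probe sets covered 34 higher and 28 lower genes. Without Ripk3, 12 of 61 called genes lay on chromosome 4, an excess whose source stays open. For the named genes other than Ripk3, loss of RIPK3 and another difference between the lines cannot be told apart. The groups did not overlap in 6.87% of genes, against 2.86% by chance. The count was 53, 43 and 53 without RIPK3 triple KO replicate 1, 3 and 4, and 49, 59 and 39 without TRAF2/Casp8 KO replicate 1, 3 and 4. Both genotypes were in plate column 7, RIPK3 triple KO in rows A to D and TRAF2/Casp8 KO in rows E to H, so genotype and row cannot be told apart here.

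The comparison of IKKβ triple KO with TRAF2/Casp8 KO asks what changes when Ikbkb is also deleted in parenchymal cells. Of the genes that passed, 22 were higher and 170 lower. Guca2b fell 14.2-fold (log2 −3.83 ± 0.35 SE, n = 4 per group, adjusted p = 8.12e-05), Rragd 7.05-fold (−2.82 ± 0.17, adjusted p = 2.02e-06) and the lymphotoxin gene Ltb 4.4-fold (−2.14 ± 0.25, adjusted p = 0.000869). Of 24 interferon-stimulated genes, 2 rose, Usp18 by 1.73-fold (0.79 ± 0.13, adjusted p = 0.00769) and Ifit1 by 2.27-fold (1.18 ± 0.21, adjusted p = 0.0128). The call of Ifit1 was lost without TRAF2/Casp8 KO replicate 1 or 4 or IKKβ triple KO replicate 3 or 4 (up to 0.06).

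Further falls were in Siglecf (6.16-fold), Serpina12 (4.42-fold), Tff3 (4.05-fold), Gask1a (3.91-fold) and Ccl20 (3.68-fold). The largest rises were in Akr1c18 (9.09-fold, log2 3.19 ± 0.55, adjusted p = 0.0116), the interleukin-22 receptor gene Il22ra1 (3.45-fold), Mettl7b (2.63-fold, adjusted p = 2.12e-05), the GABA receptor gene Gabbr2 (2.46-fold), Prg4, which encodes lubricin (2.3-fold, adjusted p = 0.0472), Ifit1, the non-coding RNA Dubr (2.1-fold) and Phf11a (2.05-fold). All 8 falls kept their call with each array left out. The call of Akr1c18 was lost without TRAF2/Casp8 KO replicate 1 (adjusted p = 0.0549) and that of Prg4 without any array but IKKβ triple KO replicate 1 (up to 0.151). That of Phf11a was lost without TRAF2/Casp8 KO replicate 3 or 4 or IKKβ triple KO replicate 3 or 4 (up to 0.0735).

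Of 12 non-canonical NF-κB genes, 4 fell (5 adjusted over the list alone): Ltb, Birc2 (log2 −0.91), Madcam1 (−1.84) and Nfkb2 (−1.03). The list median was −0.34 (camera adjusted p = 9.61e-06, adjusted p = 0.312 with an estimated correlation), and −0.58 without IKKβ triple KO replicate 2. Of 31 canonical targets, 4 fell (1 higher and 6 lower adjusted over the list alone), Ccl20, Nfkbie (−1.85), Ccl2 (−1.26) and Birc3 (−1.14), and the list test gave adjusted p = 0.0502 (0.0278 and 0.006 without TRAF2/Casp8 KO replicate 1 and 3, and 0.0424 without IKKβ triple KO replicate 2). Of 22 chemokines, 4 fell (6 adjusted over the list alone), including Ccl9 (−0.72) and Cx3cl1 (−1.05), with adjusted p = 0.00631 and adjusted p = 0.452 with an estimated correlation. Of 18 biliary and progenitor genes, Sox9 (−1.12), Cldn7 (−1.12) and Cldn4 (−1.33) fell (2 higher and 6 lower adjusted over the list alone). That list had camera adjusted p = 0.0114, 0.15 without IKKβ triple KO replicate 1, and adjusted p = 0.389 with an estimated correlation. Its median was −0.06 (−0.143 to 0.0296 with 1 array left out), and 8 of its 18 genes were higher, passing or not. Of 26 stellate cell and matrix genes, Col6a3 fell (−0.74; 7 adjusted over the list alone; adjusted p = 5.24e-07, adjusted p = 0.312 with an estimated correlation). Baat fell by 2.69-fold and Cd74 by 1.91-fold. Of 18 fetal liver and cancer-associated genes, Tff3 fell (6 adjusted over the list alone), with a median of −0.06 (−0.135 to −0.0194 with 1 array left out). That list had camera adjusted p = 0.000778 and adjusted p = 0.396 with an estimated correlation.

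Of the interferon-stimulated genes, 10 were higher adjusted over the list alone, and the list had a median of 0.47 (adjusted p = 1.42e-10, adjusted p = 0.312 with an estimated correlation). Srebf1, a regulator of lipid synthesis, rose 1.87-fold and the apolipoprotein gene Apoc3 1.85-fold. Of 15 urea cycle and amino acid genes, 0 passed and 3 were higher adjusted over the list alone, with a median of 0.23. That list had camera adjusted p = 0.00156, 0.0719 without TRAF2/Casp8 KO replicate 4, and adjusted p = 0.581 with an estimated correlation. Hal differed by 1.35 (limma adjusted p = 0.0853). Erythroid markers had a median of 0.54 (0 passed, 0 adjusted over the list alone; adjusted p = 0.0194, up to 0.328 without TRAF2/Casp8 KO replicate 1 or 2 or IKKβ triple KO replicate 3 or 4, and adjusted p = 0.758 with an estimated correlation). Without any 1 of these 4 arrays the median was 0.28 to 0.37, and it was 0.92 without IKKβ triple KO replicate 2 and 0.91 without TRAF2/Casp8 KO replicate 4. The 23 cell cycle genes had a median of 0.20 (0 passed, 0 adjusted over the list alone; adjusted p = 0.000173, adjusted p = 0.653 with an estimated correlation). Their mean signal was 7.50 in IKKβ triple KO replicate 1 against 8.30 to 8.47 in the other 3, and the median was 0.43 without that array, 0.13 without IKKβ triple KO replicate 4 and 0.32 without TRAF2/Casp8 KO replicate 4.

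In all, 223 probe sets passed, 26 higher and 197 lower, covering 22 higher and 170 lower genes. The groups did not overlap in 7.48% of genes, against 2.86% by chance. The count was 115 and 121 without TRAF2/Casp8 KO replicate 1 and 4, and 125 and 142 without IKKβ triple KO replicate 3 and 4. Both genotypes were in rows E to H but in different plate columns, so genotype and column cannot be told apart here.

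**Figure D2:**
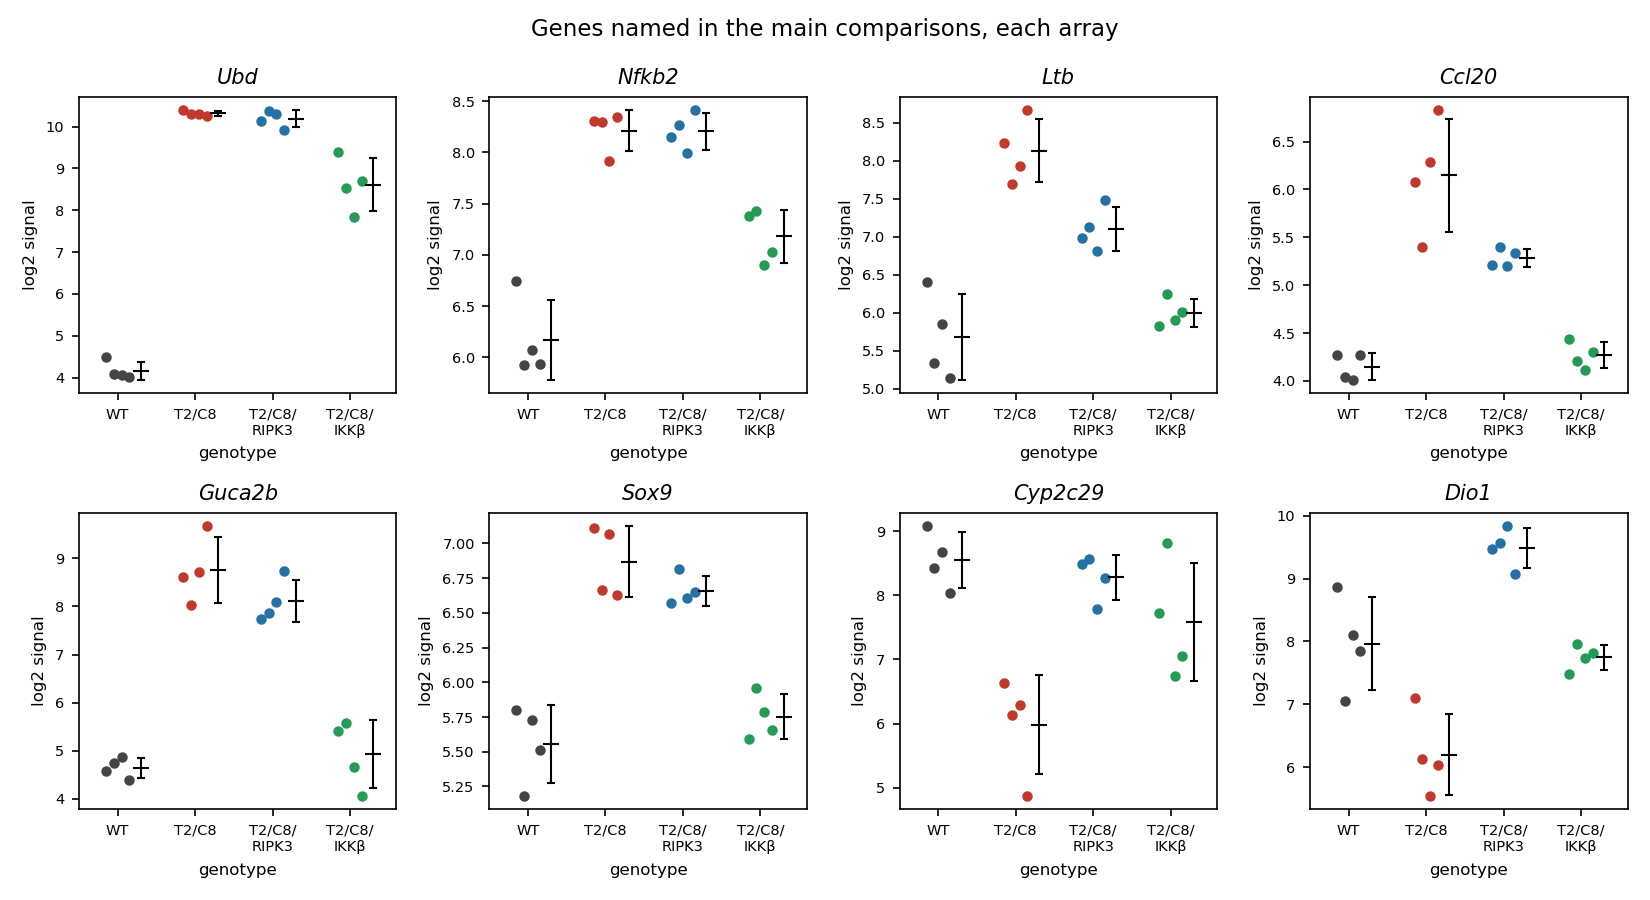
Log2 signal (y axis) of 8 named genes by genotype (x axis); each point is 1 array, and the bar beside the points is the mean with the SD (n = 4). Ubd, Nfkb2 and Ltb are high in TRAF2/Casp8 KO and lower in IKKβ triple KO, while Cyp2c29 and Dio1 are higher in RIPK3 triple KO than in TRAF2/Casp8 KO.

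**Figure D3:**
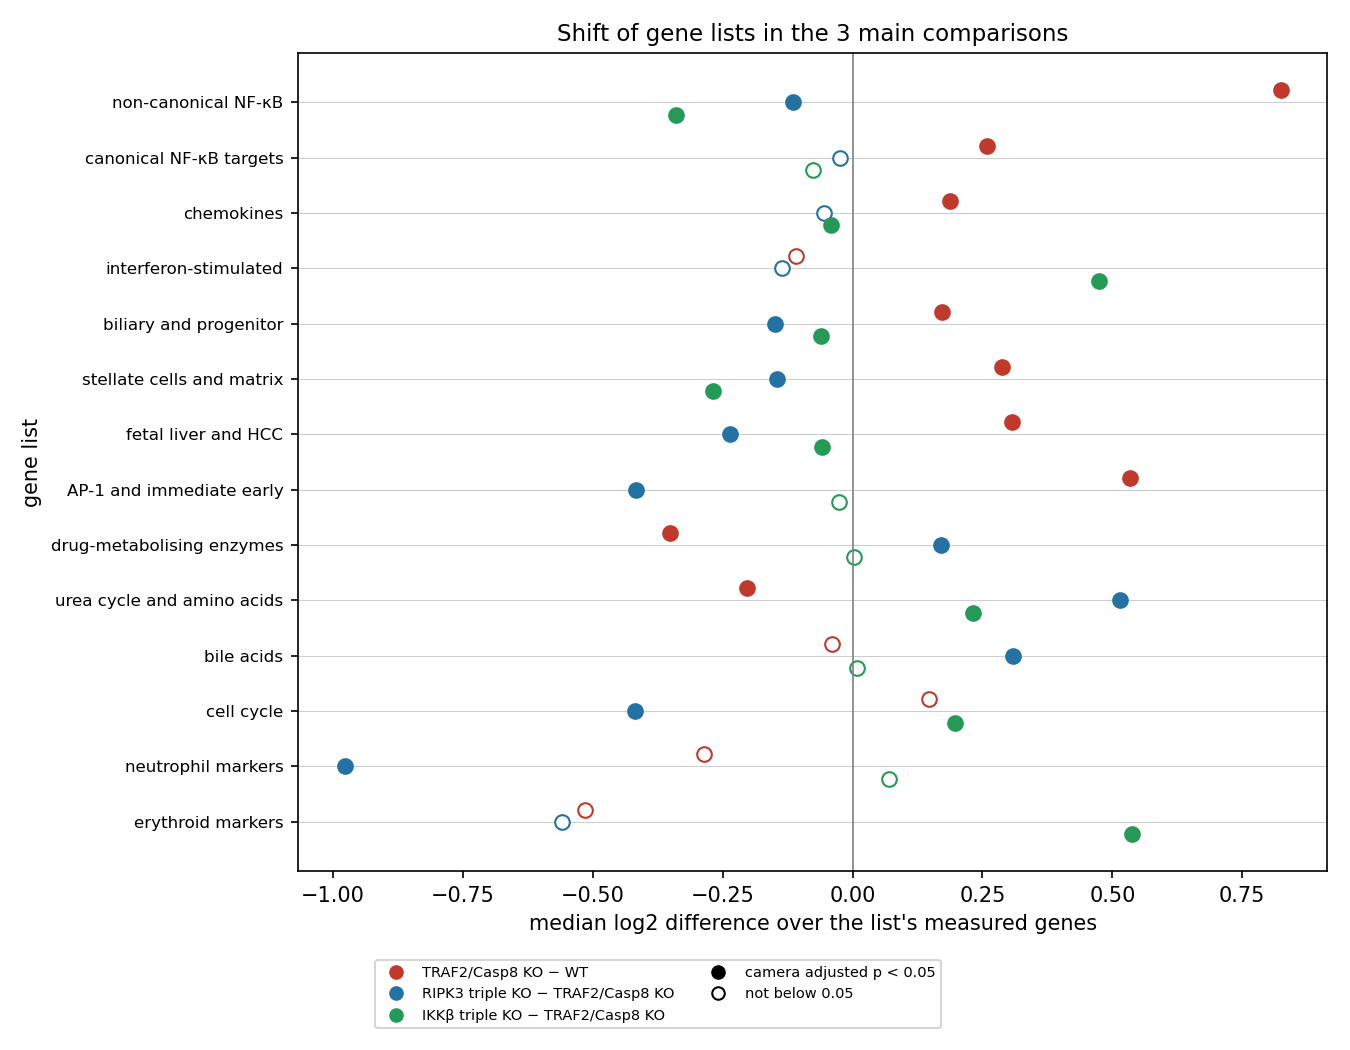
Median log2 difference (x axis) of 14 gene lists (y axis) in the 3 main comparisons; filled points have a camera adjusted p under 0.05 with the preset correlation, and 0 list tests passed with an estimated correlation. The non-canonical NF-κB list lies at 0.82 in TRAF2/Casp8 KO against WT and at −0.34 in IKKβ triple KO against TRAF2/Casp8 KO (−0.58 without IKKβ triple KO replicate 2). The list marked as neutrophil markers also holds genes of myeloid precursors.

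Of genes higher in TRAF2/Casp8 KO than in WT, 152 were lower in IKKβ triple KO than in TRAF2/Casp8 KO, and 17 went down and then up. These calls share the TRAF2/Casp8 KO arrays, which by itself can give opposite calls. With those arrays split between the 2 comparisons, 50 to 76 genes went up and then down over 6 splits (0.781 to 1.05 by chance, if calls were independent) and 1 to 5 down and then up (0.0108 to 0.0489). Across genes, which are not independent replicates, the differences correlated at r = −0.777, against −0.507 for a simulated unchanged group. With the shared arrays split, r was −0.616 to −0.477. For RIPK3 triple KO, 9 genes went up and then down and 10 down and then up; with the shared arrays split these were 0 to 9 (0.044 to 0.177 by chance) and 1 to 3 (0.0181 to 0.0596). Across genes, r was −0.408 against −0.509 simulated, a covariance of −0.0238 against −0.0117 simulated, and r of −0.296 to −0.146 with the shared arrays split. Against the same TRAF2/Casp8 KO arrays, 5 genes were higher and 9 lower in both triple knockouts, and 0 went opposite ways. Chance would give 0.0397 and 0.253, if calls were independent. Akr1c18 and Mettl7b were among the first, Ccl2 and Cldn7 among the second. Sharing those arrays by itself can give such calls, which were not counted with the arrays split. For this pair, r across genes was 0.291 against 0.478 simulated, and −0.026 to 0.198 with the shared arrays split. Genes called between TRAF2/Casp8 KO and WT (median 112.5, 44 to 268 over 36 splits) were followed on arrays not used to call them. They were shifted from WT in RIPK3 triple KO by 81% of the TRAF2/Casp8 KO shift (75.1 to 84.9%). In IKKβ triple KO the shift was 27.4% (24.1 to 37%). Taken from medians, these were 77.2% (63.5 to 85.9%) and 22.7% (16.8 to 30.5%). All RIPK3 and IKKβ triple KO arrays entered every split, so the ranges do not measure the spread among those animals. RIPK3 triple KO shares plate column 7 with TRAF2/Casp8 KO and IKKβ triple KO shares column 5 with WT, and an effect of the column would give the same order. For genes called between IKKβ triple KO and TRAF2/Casp8 KO (median 27, 5 to 113), the difference of WT from TRAF2/Casp8 KO was 126% of that of IKKβ triple KO (115 to 168%; 93.1 to 203% from medians). That of RIPK3 triple KO was 26.9% (7.04 to 39.9%; −2.55 to 39.9% from medians).

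**Figure D4:**
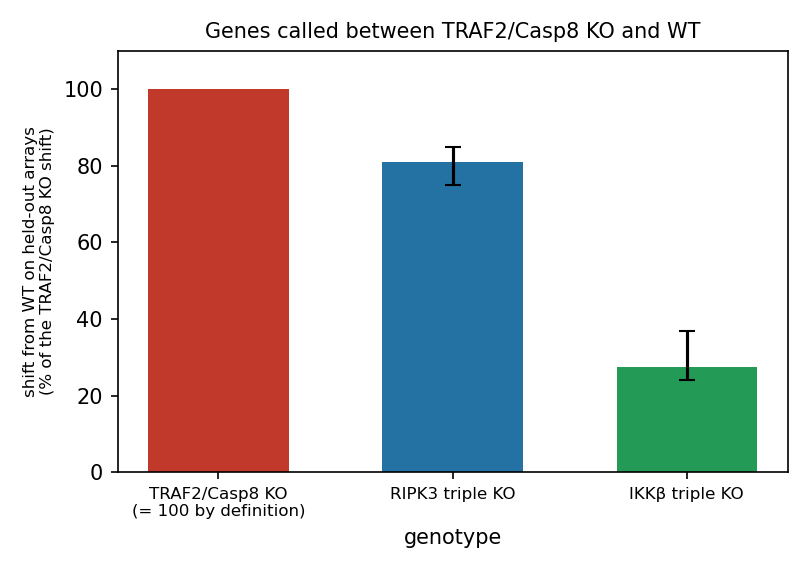
Mean shift from WT (y axis, percent of the TRAF2/Casp8 KO shift) on held-out arrays for genes called between TRAF2/Casp8 KO and WT, by genotype (x axis); bars are medians over 36 splits and lines their lowest and highest values. RIPK3 triple KO, in the plate column of TRAF2/Casp8 KO, stands at 81%, and IKKβ triple KO, in the column of WT, at 27.4%.

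Compared with WT, RIPK3 triple KO asks how livers that also lack RIPK3 differ from WT. Ubd rose 64.9-fold (log2 6.02 ± 0.23 SE, n = 4 per group, adjusted p = 2.74e-09), Ces3a 18-fold, Wif1 16.2-fold and Serpina12 14-fold. The metallothionein gene Mt2 (5.87-fold), Krt20 (5.85-fold), Slc22a26 (4.98-fold) and Samd9l (4.53-fold) fell. Of 12 non-canonical NF-κB genes, 5 rose (5 adjusted over the list alone), including Nfkb2 (log2 2.04) and Relb (1.83), with adjusted p = 4.38e-06 and adjusted p = 0.312 with an estimated correlation. Neutrophil and myeloid precursor markers had a median of −1.20, with Mmp8 (−1.57) past the threshold and 14 of 17 lower adjusted over the list alone. That list had camera adjusted p = 1.19e-10 and adjusted p = 0.396 with an estimated correlation. WT replicate 1 had the highest mean of these markers in WT (9.22 against 7.61 to 8.02), and without it the median was −0.87 (camera adjusted p = 6.16e-07). RIPK3 triple KO replicate 4 read 7.82, within the WT range, against 6.17 to 6.99 in replicates 1 to 3. The count was 845 (527 higher, 318 lower), and 445, 425 and 450 without WT replicate 2, 3 and 4, and 527 and 468 without RIPK3 triple KO replicate 1 and 3. Groups did not overlap in 9.08% of genes, against 2.86% by chance; 225 genes were higher and 79 lower in both RIPK3 triple KO and TRAF2/Casp8 KO against WT. These 2 comparisons share the WT arrays; their r across genes was 0.689, against 0.495 for a simulated unchanged group, and 0.393 to 0.481 with the WT arrays split. Split in that way, 90 to 94 genes were higher in both (1.61 to 2.20 by chance) and 12 to 17 lower (0.2 to 0.539). Both were in rows A to D, and genotype and plate column cannot be told apart here.

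Compared with WT, IKKβ triple KO asks how livers with the added deletion of Ikbkb differ from WT, within plate column 5. Ubd rose 21.8-fold (log2 4.45 ± 0.23 SE, n = 4 per group, adjusted p = 2.17e-07), Cxcl10, an interferon-inducible chemokine, 6.31-fold (2.66 ± 0.34, adjusted p = 0.00951), Wif1 4.01-fold and the corepressor gene Ctbp2 1.52-fold. Casp8 fell 1.98-fold, and Traf2 was 1.52-fold higher in the arrays labelled as deleted (adjusted p = 0.0426). Of 31 canonical NF-κB targets, Cxcl10 rose (3 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 2.15e-10, adjusted p = 0.312 with an estimated correlation), and 0.13 without WT replicate 3. Of 12 non-canonical NF-κB genes, 0 passed and 4 were higher adjusted over the list alone (adjusted p = 3.37e-05, adjusted p = 0.312 with an estimated correlation). Of 22 chemokines, Cxcl10 rose (2 adjusted over the list alone; adjusted p = 0.000783, adjusted p = 0.396 with an estimated correlation). Of 24 interferon-stimulated genes, Cxcl10 rose (6 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 7.65e-13, adjusted p = 0.312 with an estimated correlation). Other lists moved with 0 genes past the threshold. Cell cycle genes had a median of 0.35 (camera adjusted p = 3.26e-10, 0.412 with an estimated correlation), and 0.235 to 0.589 with 1 array left out. Their mean signal was 7.50 in IKKβ triple KO replicate 1, below all WT arrays (7.60 to 8.07), and 8.30 to 8.47 in replicates 2 to 4. T and NK cell genes had a median of 0.33 (0.00112 and 0.412), and 0.145 to 0.407 with 1 array left out. B cell genes had 0.21 (0.0064 and 0.557), and −0.11 to 0.439 with 1 array left out. That call was lost without WT replicate 4 or IKKβ triple KO replicate 3. Of the lists that went the other way, drug-metabolising enzymes had −0.215 (1.29e-05 and 0.312). Of 16 AP-1 and immediate early genes, 0 passed and 6 were higher adjusted over the list alone, with a median of 0.43 (adjusted p = 2.14e-10, adjusted p = 0.144 with an estimated correlation). Only 7 probe sets passed limma's threshold, 5 higher and 2 lower. Of 35556 tested, 2230 had an unadjusted limma p under 0.05, where chance alone would give a share of 0.05. In the other comparisons 3265 to 5376 did. The count was 11, 4 and 13 without WT replicate 1, 3 and 4 and 4 without IKKβ triple KO replicate 2. Groups did not overlap in 3.92% of genes, against 2.86% by chance. WT was in rows A to D and IKKβ triple KO in rows E to H, so genotype and row cannot be told apart here.

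IKKβ triple KO against RIPK3 triple KO sets the 2 additional deletions side by side. Krt20 (6.51-fold), Samd9l (5.11-fold), G0s2 (3.54-fold) and Ripk3 (3.52-fold) were higher in IKKβ triple KO, and Guca2b (9.06-fold), Serpina12 (7.11-fold), Siglecf (7-fold) and Rragd (5.99-fold) were lower. Of 23 cell cycle genes, Ccnd1 rose (log2 0.64; 17 adjusted over the list alone), with a median of 0.61 (camera adjusted p = 4.47e-14, adjusted p = 0.373 with an estimated correlation). The mean signal of these genes in IKKβ triple KO replicate 1 (7.50) lay within the range of RIPK3 triple KO (7.46 to 7.68), while the other 3 read 8.30 to 8.47, and without that array the median was 0.85. Erythroid markers had a median of 1.06 in the same comparison (0 passed, 0 adjusted over the list alone; adjusted p = 0.000793, adjusted p = 0.608 with an estimated correlation). RIPK3 triple KO replicate 4 (mean signal 7.34) stood apart from the other 3 (5.29 to 5.72), within the range of IKKβ triple KO (5.98 to 7.79), and without it the median was 1.54. Of 24 interferon-stimulated genes, Ifit1 (1.37), Oasl1 (0.80) and Irf7 (0.93) rose (13 adjusted over the list alone; adjusted p = 2.14e-10, adjusted p = 0.312 with an estimated correlation). Neutrophil and myeloid precursor markers had a median of 1.08 (0 passed, 11 adjusted over the list alone). That list had camera adjusted p = 1.47e-09 and adjusted p = 0.412 with an estimated correlation. Their mean signal was 7.82 in RIPK3 triple KO replicate 4 and 6.17 to 6.99 in replicates 1 to 3. IKKβ triple KO arrays read 7.56 to 8.53. The count was 567 (179 higher, 388 lower). It was 370, 295 and 197 without RIPK3 triple KO replicate 1, 2 and 3, and 938, 260, 306 and 230 without IKKβ triple KO replicate 1, 2, 3 and 4. Groups did not overlap in 9.01% of genes, against 2.86% by chance. The genotypes were in different columns and rows, so genotype and plate position cannot be told apart here.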

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

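The tests of exchanged labels and of the number of Traf2 probe sets were chosen after seeing the data; the splits of the arrays and the rescaling of Traf2 were planned. Of 368 groups of 4 arrays examined for a value far from the other 3 (the genes named in the text and the array medians), 19 had such a value, where chance gives about 18.4. In WT replicate 1, Ubd read 4.49 (others 4.02 to 4.09), Clec2h 5.51 (others 7.18 to 7.30) and Ier3 5.70 (others 5.10 to 5.19). In TRAF2/Casp8 KO replicate 1, Tff3 read 8.86 (others 9.40 to 9.50). In TRAF2/Casp8 KO replicate 2, Samd9l read 6.61 (others 6.97 to 7.02), Slc22a26 4.28 (others 4.93 to 4.99) and Saa3 4.03 (others 3.38 to 3.48). In TRAF2/Casp8 KO replicate 3, Nfkb2 read 7.91 (others 8.29 to 8.34) and Saa4 10.35 (others 9.92 to 9.98). In TRAF2/Casp8 KO replicate 4, Wif1 read 9.67 (others 10.35 to 10.37), Gabbr2 6.20 (others 7.24 to 7.45) and Agxt 9.27 (others 9.88 to 9.99). In RIPK3 triple KO, Nr0b2 read 6.66 in replicate 1 (others 7.28 to 7.32), Asl 10.59 in replicate 3 (others 10.02 to 10.10) and Irf7 6.84 in replicate 4 (others 7.22 to 7.27). In IKKβ triple KO, Ajuba read 5.97 in replicate 1 (others 6.62 to 6.75), Ces3a 8.50 in replicate 2 (others 10.28 to 10.47), G0s2 9.38 in replicate 3 (others 9.91 to 9.99) and Serpina12 5.04 in replicate 4 (others 4.12 to 4.24).

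Each comparison of 8 arrays has 35 splits into 4 and 4. In 5 comparisons the real split alone gave a count as large as its own (1 of 35). The counts were 800 against 2 for the highest other split in TRAF2/Casp8 KO against WT, and 94 against 1 in RIPK3 triple KO against TRAF2/Casp8 KO. They were 223 against 1 in IKKβ triple KO against TRAF2/Casp8 KO and 845 against 1 in RIPK3 triple KO against WT. In IKKβ against RIPK3 triple KO they were 567 against 5. A share of 1 of 35 is the lowest this test can reach, and it was not adjusted over the comparisons. It therefore argues against chance in these 5 comparisons but does not exclude it. In a mixed split, a difference between genotypes adds to the spread within each side, which lowers the count. Each genotype filled a part of the plate of its own, so the splits cannot tell genotype from plate position. In IKKβ triple KO against WT, 2 of 35 splits gave 7 or more, so chance cannot be excluded for that count. The other split, with WT replicates 1, 2 and 3 and IKKβ triple KO replicate 1 on a side, called 160 probe sets, which points to a structure of these samples beside genotype. The mean signal of the cell cycle genes was 7.50 to 7.96 on that side and 8.07 to 8.47 on the other, as seen afterwards. The means of erythroid markers and of neutrophil and myeloid precursor markers overlapped between the sides. Whether the cell cycle level accounts for these calls was not tested.

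The Traf2 signal was higher, not lower, in the arrays labelled as Traf2-deleted. An exchange of labels between WT and knockout arrays is argued against by Casp8, which lay below all WT arrays in 12 of 12 arrays labelled as deleted. Rescaling is argued against too, since the lowest Traf2 difference over both rescalings was 0.995 on the log2 scale. A candidate explanation that stays open is that probes outside the deleted exons read transcript of the targeted allele: the table holds 1 Traf2 probe set, and the positions of its probes were not used here. A response of Traf2 transcription to the genotype is a biological alternative that was not tested.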

How the results depend on the processing

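No alternative was chosen after seeing the data, except leaving out each array for the lists in the 3 further comparisons. The counts below are in the order TRAF2/Casp8 KO against WT, RIPK3 triple KO and IKKβ triple KO against TRAF2/Casp8 KO, RIPK3 and IKKβ triple KO against WT, and IKKβ against RIPK3 triple KO; the main counts were 800, 94, 223, 845, 7 and 567. With only the 2 groups compared they were 458, 40, 109, 328, 1 and 232 (fewer arrays estimate the spread), and with a minimum fold of 2 they were 186, 47, 76, 188, 4 and 128 (fewer probe sets qualify). Array weights gave 1594 for the first, 509 for the third, 20 for the fifth and 875 for the sixth, where the cause was not tested. Without the dimmest probe sets the fifth count was 13, with 1 probe set per gene the third was 340 and the fifth 28 (fewer rows tested), and with a replicate block the second was 62 (the cause was not tested). Leaving out each array in turn gave 420 to 902, 39 to 89, 115 to 312, 425 to 1095, 4 to 13 and 197 to 938. All 6 counts stayed within 1.5 times the main count with an intensity trend, both rescalings and the plate row as a random block (consensus correlation 0.0133), which cannot remove a difference between rows A to D and E to H. Of 51 gene results past the threshold in the 3 main comparisons, 51 kept direction and call under trend, rescalings, array weights, 1 probe set per gene and plate row; 17 lost the call with only 2 groups, 6 with a replicate block (Mug2; Akr1c18, B3galt1, Krt23 and Cyp1b1 in RIPK3 triple KO against TRAF2/Casp8 KO; Prg4) and 15 with some array left out. Of 40 list results, 40 lost the call with an estimated correlation, 3 after quantile normalisation, 2 with a replicate block and 11 with some array left out. fry, which asks another question (whether a list moves at all), passed 12 of the 40. No result changed the direction of its test past its threshold. The median of the chemokine list in IKKβ triple KO against TRAF2/Casp8 KO (−0.0406) reached 0.00733 with 1 array left out, while its call held. That of the biliary and progenitor list in the same comparison (−0.06) reached 0.0296, and its call was lost without IKKβ triple KO replicate 1. Replicate numbers were not taken to pair the arrays, since in no comparison did all 4 same-number pairs correlate above 0.1. In IKKβ triple KO against TRAF2/Casp8 KO, where same-number arrays share a plate row, 3 of 4 did (0.113, 0.111 and 0.108, the other −0.022), and a replicate block gave 176 calls. In RIPK3 triple KO against WT, where same-number arrays also share a row, 0 of 4 did (−0.099 to 0.022). Signals near background limit what a fold can show.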

Other observations

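The tests of plate column, of the neighbours of Ripk3 (with its adjustment over 4 loci), of positions along the chromosomes, of calls with shared arrays split, of marker means per array, and of lists with each array left out in the further comparisons were chosen after seeing the data; the gene lists were planned. Some marker lists that the comparisons above did not describe also moved. In TRAF2/Casp8 KO against WT, 17 T and NK cell genes had a median of 0.24, with 1 higher (1 adjusted over the list alone; camera adjusted p = 0.0124, up to 0.114 without WT replicate 2 or 4, each with a median of 0.14, against 0.40 without WT replicate 1, and adjusted p = 0.557 with an estimated correlation). In RIPK3 triple KO against WT, 20 sterol and fatty acid synthesis genes had a median of −0.41, with 2 lower (5 adjusted over the list alone; adjusted p = 0.000215, adjusted p = 0.558 with an estimated correlation). In the same comparison 12 erythroid markers had a median of −1.0, with 0 past the threshold (0 adjusted over the list alone; adjusted p = 0.00116, adjusted p = 0.632 with an estimated correlation); RIPK3 triple KO replicate 4 (mean signal 7.34) stood apart from the other 3 (5.29 to 5.72) and lay within the WT range (6.66 to 7.66), and without it the median was −1.5. In IKKβ against RIPK3 triple KO, the 20 sterol and fatty acid synthesis genes had a median of 0.53, with 1 higher (5 adjusted over the list alone; adjusted p = 1.22e-07, adjusted p = 0.396 with an estimated correlation).

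Comparisons across plate columns 5 and 7 called more probe sets than those within a column. Plate column as the whole cause of the difference between TRAF2/Casp8 KO and WT is argued against by IKKβ triple KO. That genotype shares column 5 with WT and still showed 27.4% of the shift on held-out arrays (24.1 to 37%, and 16.8 to 30.5% from medians). For the difference between IKKβ triple KO and TRAF2/Casp8 KO, the matching share within column 5 was 26% (15 to 68%), but −6.9 to 103% when taken from medians, so column and genotype cannot be told apart as its whole cause. A part of either difference may come from the column: a column term adds 0 coefficients to the 4 genotype means, so the design keeps this open beside the loss of IKKβ. WT and IKKβ triple KO also lay in different rows, so the value within column 5 speaks of the column alone, and plate position as a whole stays open.

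Alleles of another strain carried with the Ripk3 null allele stay open for calls near Ripk3 on chromosome 14. Of 200 measured neighbours of Ripk3, 3 were called between RIPK3 triple KO and TRAF2/Casp8 KO (1.5%, against 0.312% elsewhere; Fisher's exact test, two-sided, p = 0.0272, and 0.109 adjusted over the 4 targeted loci, of which Casp8 had 1 called neighbour and Traf2 and Ikbkb 0): Mmp14, Ajuba and Adcy4, named after their values were seen. Such neighbours made up 4.92% of the called genes, which argues against carried alleles among these 200 neighbours as the source of most of the calls. It does not speak of carried alleles farther away. Other segments that differ between the lines stay open: 19.7% of called genes had another called gene within 10 measured genes (median 6.56% in random sets), but such an excess was also present in the 2 other main comparisons (56.3% against 50.5%, and 29.8% against 19.4%). Chromosome 4 held 12 of 61 called genes, against 5.94% of all genes (Fisher's exact test, p = 0.00021, 0.0042 adjusted over 20 chromosomes). In the 2 other main comparisons it held 6.77% and 5.24% of called genes (Fisher's exact test, p = 0.387 and 0.877). The source of this excess stays open. The 3 probe sets that carry the symbol of the predicted gene Gm3893 alone read 4.45 to 4.86 in RIPK3 triple KO. They read 7.35 to 8.26 in all other arrays. In all, 9 probe sets list this gene, and 9 were called lower in RIPK3 triple KO than in TRAF2/Casp8 KO (log2 −2.78 to −3.39).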
